A study of Mus musculus with 8 samples.

How the data were processed

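Superior cervical ganglia of 8 mice, 4 control and 4 conditional knockout (cKO), were analysed. Per the labels' protocols, RNA was extracted from the ganglion pair of each animal, checked for integrity and made into libraries of polyadenylated RNA with a TruSeq v2 kit. The deposited table holds whole-number read counts per gene symbol, and the authors made it from reads aligned with STAR to mm10, per the submitters' processing notes. The version of STAR, the counting program, the gene annotation and the use of strand are not given in the sources used here. Reads of genes that overlap or resemble each other may therefore have been shared or dropped in ways that cannot be seen in the table.

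The table had 23827 rows, of which 4192 were at 0 in every library. Some symbols stood on more than 1 row (262 symbols on 738 rows, 23 of them tested), and 165 rows joined several symbols, 1 of them tested. No row named a mitochondrially encoded gene, so that list was not tested. Columns were assigned to libraries by the sample titles. Coordinates come from GENCODE vM21 on GRCm38, the assembly also called mm10, to which 97.9% of the 23351 distinct names were matched. Of 87 named genes with coordinates, 16 overlap another tested gene.

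Total counts per library were between 16214912 and 18114418. Replicates of a group differed by more than sampling noise, with chi-square values per gene from 8.08 to 58.4, so each library was counted as a replicate. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust dispersion and quasi-likelihood fit, group as the only term), with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Means and SDs are in CPM with TMM-scaled library sizes, and log2 CPM used a prior count of 2. Exact permutation tests used all 70 assignments of the libraries to groups of 4 and were two-sided.

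Gene lists were fixed before the data were examined, 26 in all, and 22 pathway and cell type lists with at least 5 tested members formed a family tested with camera (limma 3.58.1, correlation 0.01). Camera with a correlation estimated for each list and fry stood beside it. The named genes followed a rule also fixed beforehand: Kif1b and another gene in any case; the 12 genes with the largest changes each way among those that passed, at a mean of 5 CPM or more and without overlap of the groups; the 5 with the smallest p each way; up to 4 passing members of each list or, where none passed, the 2 with the smallest p; and Th, Dbh, Ngfr, Sox10, Mki67 and another gene in any case. Predicted genes were counted but could be left unnamed. Some genes that the rule takes are not reported here, though counts of genes include them. Olfr594, Olfr560, Trim68, Sardh, Gm13399, Atp6v1b2, Rgs5, Pnmt, H2-Aa and H2-Eb1 were chosen after their values were seen, as were the neighbours of Dbh and members of lists or families named beyond the rule.

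The alternatives were the size factors of DESeq2 in edgeR, library size alone, no filter beyond 1 count in total, a filter of 1 CPM in at least 4 libraries, the Wald test of DESeq2 1.42.0, limma voom with and without sample weights, a block for the number in the sample label, a covariate for Y-linked genes and each library left out. The steps were tested on simulated counts for the comparison of cKO with control over 14592 genes. There 23.9% of genes changed by 1.5-fold, 83.6% of those changed by 2-fold and 100% of those changed by 4-fold were recovered, and 4.73% of calls were false. A seeded list passed camera and 0 of 20 random lists did. These simulated genes were drawn independently of each other, so the test says nothing of lists whose members vary together. Figures were drawn with matplotlib 3.10.9.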

Results

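Gene expression was measured by sequencing polyadenylated RNA from the superior cervical ganglia of mice on postnatal day 1. These paired ganglia at the top of the sympathetic chain hold noradrenergic neurons together with glia, blood vessels and connective tissue. Control animals carried a Kif1b beta allele flanked by loxP sites and no Cre recombinase. Conditional knockout (cKO) animals carried the same allele and Cre under the promoter of Dbh, the gene for dopamine beta-hydroxylase, which noradrenergic cells express. There were 4 control and 4 cKO libraries, each from the ganglion pair of a separate animal. Total counts lay between 16214912 and 18114418 per library. All 8 libraries held at least 16729 Xist counts and at most 1 count over 4 Y-linked genes.

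The comparison asked how loss of the motor protein KIF1B beta from sympathetic neurons altered gene expression in the ganglion. Kif1b, the targeted gene (chromosome 4, 149176319 to 149307693, minus strand, GRCm38), had 1224 ± 222 CPM (counts scaled to library size; SD, n = 4) in control and 260 ± 52.7 CPM in cKO ganglia (SD, n = 4). It fell by 2.24 on the log2 scale (SE 0.18) with an adjusted p of 3.43e-04 in edgeR's quasi-likelihood test, and each cKO library lay below each control library. The exact two-sided permutation p was 0.0286, the smallest that 70 assignments of the libraries allow. The count joined all isoforms of the gene and all cells of the ganglion, including those without Cre. The noradrenergic genes Th and Dbh had log2 fold changes of -0.12 (SE 0.09) and -0.19 (SE 0.09), and Ngfr, the low-affinity neurotrophin receptor, had -0.32 (SE 0.18). None of these passed.

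**Figure D1:**
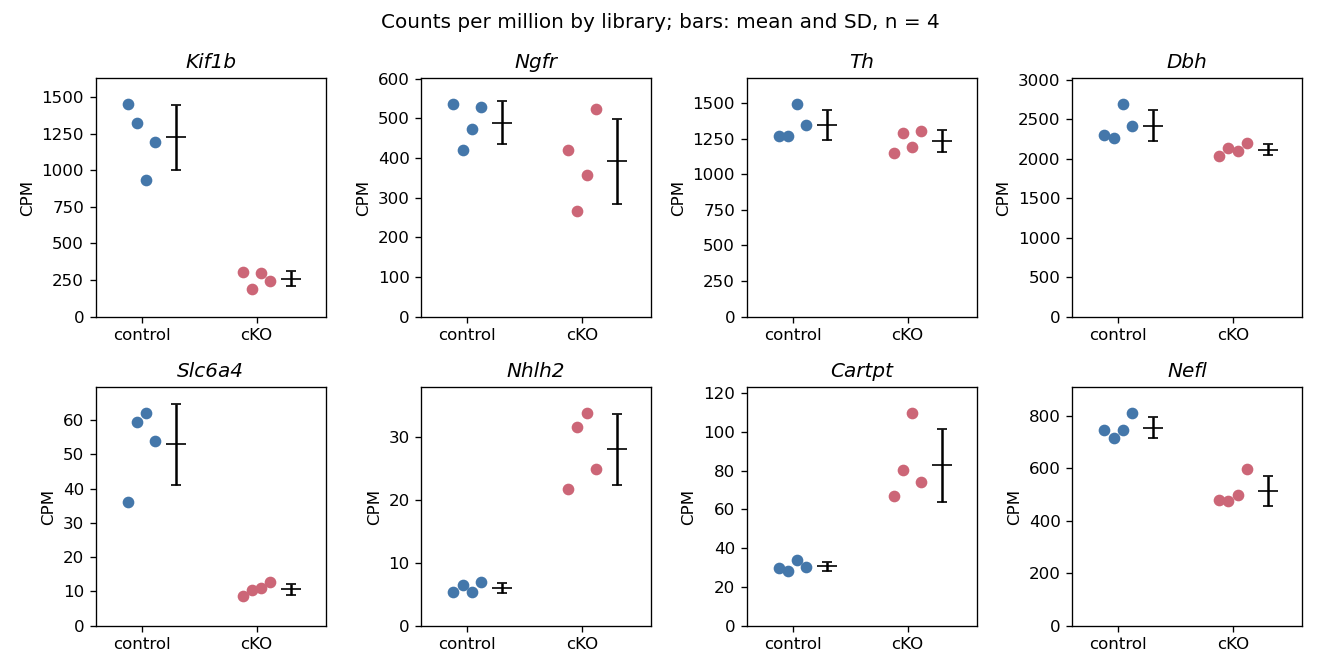
CPM values (vertical axes) of 8 genes in each library (points, 4 control and 4 cKO), with the mean and SD of each group (bars), on linear axes from 0. Kif1b averaged 1224 CPM in control and 260 CPM in cKO libraries, while the groups overlapped for Ngfr and Th.

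Of 14592 tested genes, 397 (2.72%) changed at an adjusted p below 0.05, 234 higher and 163 lower in cKO ganglia. A change of at least 2-fold was seen in 58 of the genes that rose and 54 of those that fell. Groups did not overlap in 1607 tested genes, 11% of those tested, where chance gives 2.86% on average over all assignments. Genes that vary together can move this share far from its average. The share was not computed for other splits, so it is no test of chance. Scaling by library size alone gave 343 genes higher and 145 lower. Leaving out 1 library, which also lowers power, changed the count: it was 79 without control 2, 249 without control 3, 74 without control 4, 147 without cKO 2 and 137 without cKO 3. Every gene counted without control 2 or without control 4 was among the 397. All 397 kept their direction with each library left out. As groups did not overlap in 396 of them, this was nearly fixed in advance.

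The genes that rose most, among those at 5 CPM or more with groups that did not overlap, were led by Nhlh2, a neuronal transcription factor, which rose from 6.0 ± 0.80 to 28.0 ± 5.6 CPM (log2 fold change 2.22, SE 0.17, edgeR adjusted p = 3.43e-04). Next came Cbln2, a synaptic organiser, and Kcna1, a voltage-gated potassium channel, with log2 fold changes of 1.70 (SE 0.30) and 1.64 (SE 0.20). Efhd1, the class II histocompatibility gene H2-Ab1, the potassium channel partner Kcnip1 and the amino acid transporter Slc38a4 rose by between 1.51 and 1.57 on the log2 scale. Gdf10, Sfrp2, the neuropeptide gene Cartpt, Cd74 and Sytl4 rose by between 1.39 and 1.49. Cartpt went from 30.5 ± 2.5 to 82.8 ± 18.8 CPM, and the neuropeptide precursor Pnoc from 1.90 ± 0.47 to 6.89 ± 0.37 CPM. Calls of Cbln2, Sfrp2 and Cd74 were lost when control 4 was left out, those of Cbln2 and Sfrp2 also without control 2 or cKO 3, and that of Sfrp2 also without control 1, control 3, cKO 2 or cKO 4.

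Slc6a4, the serotonin transporter, fell from 52.9 ± 11.7 to 10.6 ± 1.7 CPM (log2 fold change -2.32, SE 0.19, edgeR adjusted p = 3.43e-04). Lrp1b, a lipoprotein receptor relative, had a log2 fold change of -2.14 (SE 0.19), and Prkg2, a cyclic GMP-dependent kinase, one of -1.52 (SE 0.11). Grin3a, Dsg2, Ano2, Fam196b, Tenm1, Nlrc5 and Serpina3n fell with log2 fold changes between -1.82 and -1.47. Fam196b overlaps Dock2 on the opposite strand. The calls of Tenm1 and Serpina3n were lost without control 2, control 4 or cKO 2, and that of Serpina3n also without cKO 3.

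Of 24 tested noradrenergic genes 1 rose, Cartpt, and 2 fell, among them Slc18a1, a vesicular monoamine transporter, while 21 did not pass. Slc18a1 overlaps Atp6v1b2, which had a log2 fold change of -0.42 (SE 0.10), on the opposite strand. Adjusted over the list alone, 3 rose and 4 fell. The list as a whole did not pass (camera adjusted p = 0.335). Of 28 axon and cytoskeleton genes, 3 fell and none rose. Cntn1, a neural adhesion molecule, had a log2 fold change of -0.62 (SE 0.11), and the neurofilament genes Nefl and Nefm had -0.56 (SE 0.10) and -0.51 (SE 0.11). Nefl and Nefm overlap on opposite strands in the annotation, and whether counting used strand is not given in the sources used here. Adjusted over the list alone, 8 fell. The list was lower in cKO ganglia (camera adjusted p = 1.03e-07), but not with an estimated correlation (adjusted p = 0.0809). Of 32 synaptic vesicle genes, Rab3c and Syt4 fell, by 0.64 and 0.54 on the log2 scale, and 9 fell adjusted over the list alone. That list was lower by camera (adjusted p = 9.93e-09) and not with an estimated correlation (adjusted p = 0.197).

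Of 39 neuronal channel and receptor genes, Kcna1 rose, and Kcnd2, a potassium channel, and Adra2a, an adrenergic receptor, fell. Adjusted over the list alone, 1 rose and 4 fell. The list was lower by camera (adjusted p = 0.0049), though not with an estimated correlation (adjusted p = 0.623), without control 1 (adjusted p = 0.161) or without cKO 2 (adjusted p = 0.113). Its median of -0.20 went to -0.13 and -0.09 without these libraries. Among 36 kinesin and dynein genes only Kif1b changed, also adjusted over the list alone. The list was lower by camera (adjusted p = 1.09e-04; adjusted p = 0.397 with an estimated correlation). Kif1b, deleted by design, is a member. The other 35 genes had a mean log2 fold change of -0.14 (camera adjusted p = 6.84e-04, or 0.461 with an estimated correlation). With 1 library left out, that mean ranged from -0.199 without cKO 1 to -0.0861 without cKO 2. Of 19 neurotrophic receptor and ligand genes, Gdnf, a neurotrophic factor at 0.226 ± 0.114 CPM in control and 1.10 ± 0.50 CPM in cKO ganglia, and Ntrk3, the neurotrophin-3 receptor, rose, and 3 rose adjusted over the list alone. The list was higher by camera (adjusted p = 0.0192; adjusted p = 0.397 with an estimated correlation), a call lost without control 3 (adjusted p = 0.0909) or cKO 1 (adjusted p = 0.0707). Several calls of the genes named here were lost when 1 library was left out. The log2 fold changes of Nefl then lay between -0.642 and -0.524 and those of Nefm between -0.622 and -0.445. Without control 2 or without control 4, Cntn1, Nefl, Nefm, Rab3c, Syt4, Slc18a1, Adra2a, Gdnf and Ntrk3 no longer passed. Cntn1 and Nefl were also lost without cKO 2 or cKO 3, Slc18a1 without control 3 or cKO 3, Adra2a and Gdnf without control 3, cKO 2, cKO 3 or cKO 4, Ntrk3 without control 3 or any cKO library, and Nefm without each library except cKO 4.

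Of 20 blood vessel genes 5 rose and none fell, among them the endothelial genes Pecam1 and Eng and the mural cell genes Pdgfrb and Notch3, with log2 fold changes from 0.54 to 0.79. With p adjusted over the list alone, 19 rose. The median was 0.56 (camera adjusted p = 7.87e-14; adjusted p = 0.0809 with an estimated correlation). Of 18 fibroblast and matrix genes 9 rose, among them Pdgfra, a platelet-derived growth factor receptor, from 32.5 ± 6.6 to 65.9 ± 7.6 CPM, and Ogn, Prrx1 and Col1a2, while Thy1, which neurons also express, fell. Adjusted over the list alone, 15 rose and 1 fell. The median was 0.61 (camera adjusted p = 7.12e-11; adjusted p = 0.197 with an estimated correlation). Of 23 glial genes, 4 rose: Mbp, a myelin protein gene, Art3, Apoe and Ttyh1, with log2 fold changes from 0.41 to 1.03. A total of 14 rose adjusted over the list alone. The median was 0.51 (camera adjusted p = 1.14e-08; adjusted p = 0.0809 with an estimated correlation). With 1 library left out, the medians of blood vessel, fibroblast and glial genes lay between 0.513 and 0.657, 0.568 and 0.682, and 0.414 and 0.62. Sox10, a glial transcription factor, had a log2 fold change of 0.68 (SE 0.18, edgeR adjusted p = 0.0704). Without control 4, the calls of Pecam1, Eng, Pdgfrb, Notch3, Prrx1, Col1a2, Mbp, Art3, Apoe and Ttyh1 were lost, and all of these except Mbp were also lost without control 2. Further losses were those of Pecam1 and Art3 without cKO 3, Col1a2 without cKO 2, Apoe without cKO 2, cKO 3 or cKO 4, and Ttyh1 without control 3 or any cKO library. Pdgfrb, Notch3 and Eng no longer passed without control 3 or cKO 3, Pdgfrb also without cKO 1, Notch3 and Eng also without cKO 2, and Eng also without cKO 4.

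**Figure D2:**
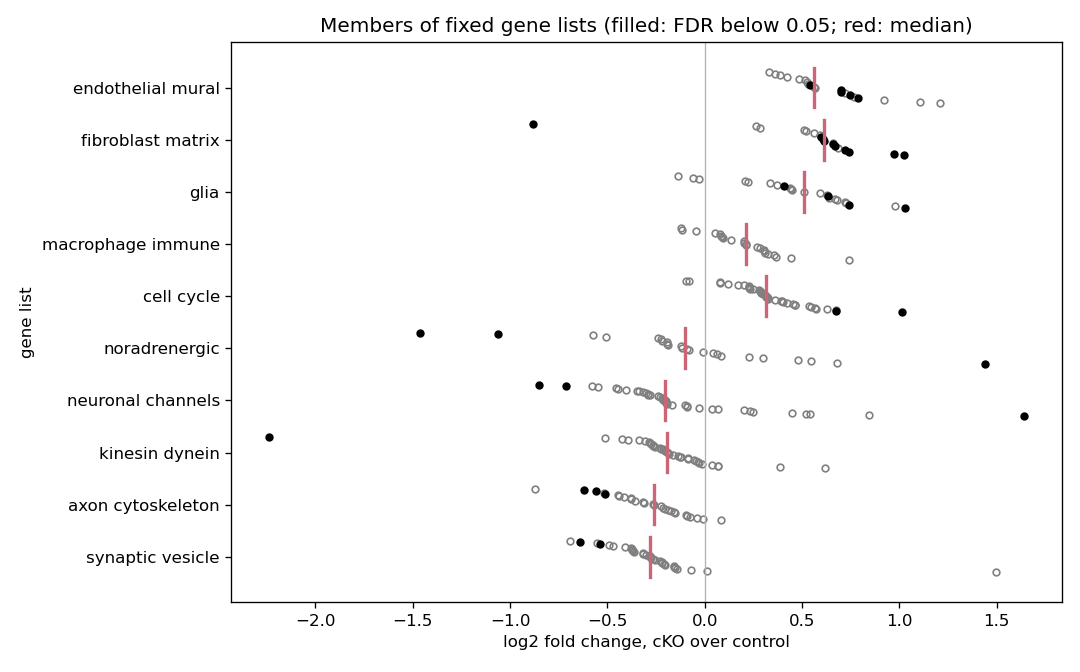
Log2 fold changes (horizontal axis, cKO over control) of the tested members of 10 gene lists. Each point is a gene, filled points passed the edgeR test and red lines mark list medians, which lay at 0.56 for blood vessel genes and -0.28 for synaptic vesicle genes.

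No macrophage gene passed among 23, also adjusted over the list alone. Ptprc and Ctss had log2 fold changes of 0.35 (SE 0.15) and 0.31 (SE 0.17). The list was higher by camera (adjusted p = 0.0314; adjusted p = 0.623 with an estimated correlation), a call lost without control 2 (adjusted p = 0.321), control 4 (0.0946), cKO 1 (0.129) or cKO 3 (0.352). Its median of 0.21 ranged from 0.0863 to 0.353 with 1 library left out. Of 40 cell division genes, Ccnd1, a G1 cyclin, and Mcm7, a replication helicase subunit, rose, by 1.01 (SE 0.21) and 0.67 (SE 0.10) on the log2 scale, and 3 rose adjusted over the list alone. The list was higher by camera (adjusted p = 9.93e-09; adjusted p = 0.397 with an estimated correlation), and Mki67 had a log2 fold change of 0.31 (SE 0.16) that did not pass. Of 8 chromaffin and glomus cell genes Cox4i2 rose and Olfr78 fell, and 5 rose and 1 fell adjusted over the list alone. That list was higher by camera (adjusted p = 0.0172; adjusted p = 0.212 with an estimated correlation). It shares Rgs5 with the blood vessel list, without which camera gave an adjusted p of 0.0318, or 0.0595 without control 2 and 0.0551 without cKO 3, and Pnmt, the adrenaline-synthesis gene of chromaffin cells, had a log2 fold change of 0.03 (SE 0.17). None of 20 cholesterol synthesis genes passed, also adjusted over the list alone, and Dhcr7 and Lss had log2 fold changes of -0.38 (SE 0.10) and -0.56 (SE 0.21). The list was lower by camera (adjusted p = 0.00148; adjusted p = 0.623 with an estimated correlation), a call lost without cKO 1 (adjusted p = 0.103). The calls of Ccnd1, Mcm7 and Cox4i2 were lost without control 4, and those of Ccnd1 and Cox4i2 also without control 2, and that of Ccnd1 also without control 3, cKO 1, cKO 2 or cKO 3. Altogether 12 of 22 lists passed camera, 8 of them with each library left out, and 0 passed with an estimated correlation. Fry passed 6: the vessel, glial and axon lists (fry adjusted p = 0.00514 each), fibroblast (0.0144), vesicle (0.0206) and chromaffin lists (0.0352). The fry calls of the fibroblast, vesicle and chromaffin lists were each lost without at least 1 library. Estimated correlations, such as 0.543 for cell division and 0.637 for cholesterol genes, exceeded the 0.01 that camera used. The exact permutation p of list means was 0.0286, the smallest possible, for vessel, fibroblast, glial, axon, vesicle, neurotrophic and chromaffin lists. It was 0.0857 for cell division and for kinesin and dynein, 0.286 for cholesterol, 0.4 for macrophage and 0.514 for channel lists.

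The remaining lists of the family did not pass camera with all libraries. Of 30 apoptosis and p53 genes Egln3, a prolyl hydroxylase, rose from 52.3 ± 6.2 to 129 ± 25 CPM (camera adjusted p = 0.0553), and 2 rose adjusted over the list alone. Of 22 neuroblastoma genes Kif1b and Lin28b fell, also adjusted over the list alone (camera adjusted p = 0.0653, or 0.212 for the 21 genes other than Kif1b). Of 13 cholinergic and peptidergic genes Penk, an enkephalin precursor, rose, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.194). Of 74 genes taken as respiratory chain genes by the pattern of their symbols, only Ndufa4l2 passed, and rose, also adjusted over the list alone (camera adjusted p = 0.35). The pattern does not show that each of these genes encodes a part of the chain. The calls of Lin28b, Penk and Ndufa4l2 were lost without control 2 or without control 4, that of Lin28b also without cKO 2, cKO 3 or cKO 4, and that of Penk also without control 3 or any cKO library. With 1 library left out, camera passed the apoptosis list without control 1 (adjusted p = 0.0138), cKO 2 (0.0243) or cKO 4 (0.0403). It also passed that list with all libraries and the Y-linked covariate (0.044). The neuroblastoma list passed without control 3 (0.0128, or 0.0604 with Kif1b taken out of the list) or cKO 1 (0.00784, or 0.0404). The cholinergic list passed without control 1 (0.0414). The respiratory chain list, lower, passed without control 1 (0.00245), cKO 2 (0.0243) or cKO 4 (0.00495). With an estimated correlation none of these lists passed in the same settings, where the smallest adjusted p was 0.2.

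No gene passed among 26 genes inducible by nerve growth factor (camera adjusted p = 0.18), where Fos and Etv4 had log2 fold changes of 0.42 (SE 0.17) and 0.51 (SE 0.20), and 0 passed adjusted over the list alone. That list was higher by camera without cKO 2 (adjusted p = 0.0487), but not with an estimated correlation (adjusted p = 0.576). None passed among 23 axon injury genes (camera adjusted p = 0.373), with Flrt3 at 0.60 (SE 0.14) and Ddit3 at 0.21 (SE 0.11), and 1 rose adjusted over the list alone. None passed among 24 interferon-stimulated genes (camera adjusted p = 0.35), of which 16 had positive and 8 negative log2 fold changes (median 0.35). The 2 with the smallest p were Trim25 at -0.48 (SE 0.12) and Stat2 at -0.46 (SE 0.11). Adjusted over the list alone, 3 interferon-stimulated genes rose and 4 fell. None passed among 15 muscle and cartilage genes (camera adjusted p = 0.18), with Col11a1 at 0.45 (SE 0.16) and Actc1 at 1.16 (SE 0.49), or among 9 sensory neuron genes (camera adjusted p = 0.482), with Prrxl1 at 1.35 (SE 0.39) and P2rx3 at 0.70 (SE 0.49). Adjusted over the list alone, 0 muscle and cartilage genes and 1 sensory neuron gene passed. The muscle and cartilage list was higher by camera without control 1 (adjusted p = 0.0137) or cKO 2 (0.0331), and with a block for the label number (0.0379). Camera with an estimated correlation did not pass it in these settings (adjusted p = 0.555, 0.604 and 0.502). Only 3 red blood cell genes were tested, none of which passed, and Hbb-b1 and Alas2 had log2 fold changes of 0.56 (SE 1.05) and 0.49 (SE 0.97). Among 80 ribosomal protein genes, tested apart, none passed, with Rplp0 at 0.26 (SE 0.12) and Rpl7a at 0.27 (SE 0.12). That list was higher by camera (adjusted p = 0.0419; adjusted p = 0.717 with an estimated correlation). Xist had a log2 fold change of 0.06 (SE 0.26).

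Libraries also differed in ways that did not follow the groups. The first principal component of log2 CPM held 37.1% of the variance and set control 1 and cKO 1 apart, and the second held 28.5% and separated the groups. The mean log2 CPM of muscle and cartilage genes was 2.40 in control 1 and 3.37 in cKO 1, and between 0.895 and 1.40 in the other 6 libraries. Sensory neuron genes averaged 3.34 in control 4 and 4.31 in cKO 4, and at most 2.15 in the others. Leaving out both control 1 and cKO 1, an alternative chosen after seeing the data, gave 437 genes, 282 higher and 155 lower, of which 296 were among the 397.

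**Figure D3:**
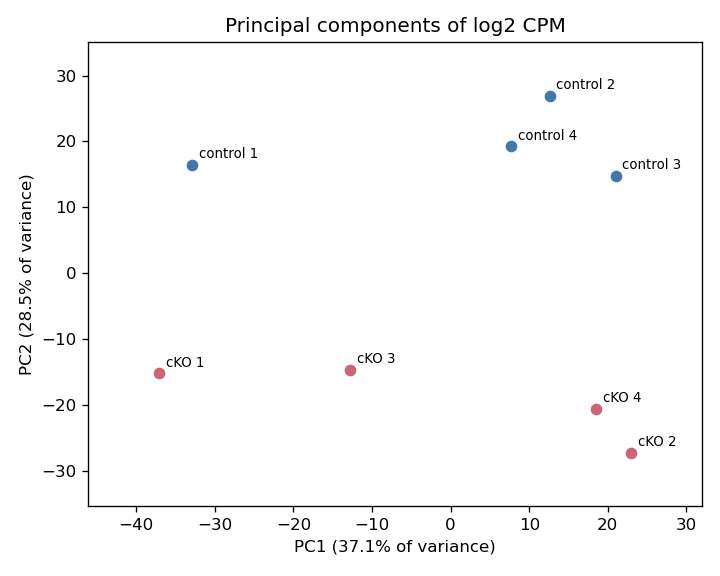
First and second principal components of log2 CPM for the 8 libraries. The first (37.1% of variance) sets control 1 and cKO 1 apart from most others, and the second (28.5%) separates control from cKO libraries.

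The smallest p-values among genes that rose belonged to olfactory receptor genes on chromosome 7. Olfr574 (102948467 to 102949507, plus strand, GRCm38) had 4 counts over the control and 373 over the cKO libraries, a ratio of 87.7 (95% interval 33.9 to 323, counting error only). Olfr570 (102894577 to 102901710, plus strand) had 1 and 646 counts, a ratio of 607 (109 to 24000). Olfr594 (103216996 to 103222313, plus strand), chosen after its values were seen, had 0 and 62 counts and was at least 19.4-fold higher, with a floor of 3 counts over the control group. Receptors of this family resemble each other, and how reads matching several of them were counted is not given in the sources used here.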

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

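All tests of explanations in this part except those of other splits and of transcript length and GC content were chosen after the result was seen. In 220 groups of 4 values, 17 (7.73%) had a library far from the others, where chance gives about 1 in 20. Of these, 13 concerned control 1 (8) or cKO 1 (5). In control 1, Mbp was high at 108 CPM, Pecam1 at 47.2, Hbb-b1 at 3.25, Alas2 at 35.6 and Olfr570 at 0.061, which is 1 count, while Olfr78 was low at 167 CPM. Its mean log2 CPM was high for genes inducible by nerve growth factor (3.97) and low for cholesterol genes (6.37). In cKO 1, Penk was high at 38.7 CPM, Notch3 at 59.7, Hbb-b1 at 6.63 and Alas2 at 59.8, and muscle and cartilage genes averaged 3.37 on the log2 scale. Elsewhere, Sfrp2 (7.21 CPM) and Prkg2 (50.0 CPM) were high in control 2, Mcm7 was high in cKO 2 (40.8 CPM) and sensory neuron genes averaged 4.31 in cKO 4.

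Among the 35 splits of the libraries into 4 and 4, only the real split, 1 of 35, gave as many as 397 genes, and the highest of the other splits gave 0. As 1 of 35 is the smallest share that these splits allow, that count speaks against chance but cannot exclude it. By unadjusted p under 0.05, however, the real split held 2457 genes and 4 other splits held more, up to 4096 for control 1, control 2, cKO 1 and cKO 3 against the rest, whose smallest edgeR adjusted p was 0.0584. That points to a structure of the samples at least as large, by this measure, as the difference between groups.

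By camera, though not with an estimated correlation (adjusted p from 0.0809 to 0.197), blood vessel, fibroblast and glial lists were higher and axon and synaptic lists lower in cKO ganglia. Muscle-rich tissue taken at dissection is argued against as the whole cause of the rises. Without control 1 and cKO 1, muscle and cartilage genes had a median of -0.0276, while blood vessel, fibroblast and glial markers together had 0.611. With all libraries these markers had 0.593, but the libraries left out were 1 from each group, so that small change says little by itself. Neighbouring tissue without muscle was not tested and stays open. Length and GC content of the longest annotated transcript are argued against too. The difference between the medians was 0.872 before and 0.909 (SE 0.0704, with genes taken as independent) after removing their trend. The genomic length of genes was not tested. A lower share of neurons stays open: the rises of 4 other cell types, from 0.205 for macrophage to 0.627 for blood vessel genes, were not shown to differ (exact permutation p = 0.257), nor were the shifts of noradrenergic (-0.0554), axon (-0.305) and vesicle genes (-0.276; exact permutation p = 0.0571). Lower expression within neurons stays open as well.

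Olfactory receptor genes within a stretch of chromosome 7 were nearly absent from control and present in all 4 cKO libraries. Summed counts of such genes on other chromosomes had a log2 ratio of 0.307 (SE 0.173), which argues against a like rise of receptor reads in general. Reads that came from a gene elsewhere but were counted in this stretch would be missing from that sum. Such reads therefore stay open as a source. A local effect, such as an inserted transgene might have, stays open, as does sharing of reads between similar neighbours. The other 15 receptors between Olfr570 and Olfr594, taken by position, had 2 counts in control and 87 in cKO libraries (exact permutation p = 0.0286, the smallest possible). The stretch was bounded by receptors that rose, and some of the 15 had been seen to be higher. This p is therefore no independent support. Within 1 Mb, 49 receptors beyond Olfr594 had 0 and 3 counts, and 23 before Olfr570 had 11624 and 7778, or 130 and 200 without Olfr78 and Olfr560, which overlap; Olfr78 fell, as did its neighbour Trim68, whose call was lost without any single library other than cKO 1. Loss of Kif1b and presence of Cre cannot be told apart, because 0 libraries carried Cre with intact Kif1b or the reverse, and this holds for each change in the comparison.

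Sardh, which lies 5192 bp from Dbh on chromosome 2, had a log2 fold change of 1.04 (SE 0.13, edgeR adjusted p = 0.00475), while Dbh itself had -0.19 (SE 0.09). Gm13399, 2529 bp from Dbh on the other side, rose too, by 0.885 (SE 0.106, edgeR adjusted p = 0.00321). Extra copies that reach the next gene in the table on either side are argued against by Fam163b, 22741 bp from Dbh beyond Gm13399, at 0.044 (SE 0.106), and Vav2, beyond Sardh, at -0.26 (SE 0.17). Extra copies of Sardh and Gm13399 carried by the Cre transgene stay open, as does regulation of both genes.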

How the results depend on the processing

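The alternatives without both libraries numbered 1 and with Kif1b or Rgs5 taken out of the lists were chosen after seeing the data. Against 397 genes (234 higher, 163 lower), DESeq2's Wald test gave 1012 (565 and 447), voom with sample weights 1539 (883 and 656) and the Y-linked covariate 189 (99 and 90). That covariate rests on 1 read each in control 4 and cKO 3, and why it gave fewer genes was not tested. With a replicate block for the label number the count was 687 (425 and 262). After each gene's group mean was subtracted from log2 CPM, same-numbered libraries correlated at 0.725, 0.352, -0.302 and 0.265. Not every library correlated best with its own number, and the labels state no pairing. Leaving out 1 library gave 74 to 514 genes, 33 to 318 higher and 40 to 196 lower. It moved the count by over 1.5 times without control 2 (79), control 3 (249), control 4 (74), cKO 2 (147) and cKO 3 (137), and the count of higher genes also without cKO 4 (153). Fewer samples lower the power; why these libraries count most was not tested. The Kif1b log2 fold change stayed between -2.349 and -2.114 and past the threshold. Camera passed 12 lists, 5 of them of cell types; 0 and 0 passed with an estimated correlation, and 6 and 4 by fry, while 12 and 5 passed with Kif1b or with Rgs5 taken out. With 1 library left out 10 to 15 and 4 to 6 passed, not always the same ones: 9 to 12 of the 12 were among them, 4 of the 12 were lost at least once and 6 others passed at least once. The cause was not tested. Of 63 passing named genes 0 reversed, which the lack of overlap between their groups largely fixed in advance. Of the 63, 30 passed under every alternative that tested them, though the filter of 1 CPM left Olfr594 untested. The other 33 were lost under at least 1, 18 of them only when 1 library was left out. With all libraries 14 were lost, each of them with the Y-linked covariate. Of these 14, Penk was also lost with the size factors of DESeq2 and Nefm with library size alone. Ntrk3 and Ttyh1 were also lost without the filter. Reversals concerned genes that did not pass. Hbb-b1 was at -0.605 by voom and -0.874 with weights, and Alas2 at -0.155 without both libraries numbered 1. With 1 library left out, Hbb-b1 ranged from -2.14 to 1.62, Alas2 from -1.28 to 1.59, Xist from -0.189 to 0.26 and P2rx3 from -0.0172 to 0.955, the lowest without cKO 1 except for P2rx3, where it was without cKO 4. In simulation 23.9% of 1.5-fold changes were recovered, so small changes are limited by 4 libraries per group.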

Other observations

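The tests of gene families in this part were chosen after the changed genes were seen. Collagen genes were over-represented among genes higher in cKO ganglia: 7 of 42 tested genes whose symbols start with Col rose (Col1a2, Col3a1, Col5a1, Col5a2, Col6a1, Col6a3 and Col18a1; smallest adjusted Fisher's exact p over the families = 0.00073). Some of them are also in the fibroblast list, so the 2 results are not independent. Fisher's exact test takes genes as independent, while the fibroblast list had an estimated correlation of 0.451. This p may therefore be too small, and over-representation that allows for correlation was not tested. Among genes lower in cKO ganglia no family passed, and the smallest adjusted p was 0.181.

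The class II histocompatibility genes H2-Aa, H2-Ab1 and H2-Eb1 and their partner Cd74, in part chosen after their values were seen, rose by 1.39 (SE 0.22), 1.54 (SE 0.21), 1.29 (SE 0.26) and 1.43 (SE 0.23) on the log2 scale. Of 15 tested H2 genes 3 rose, which did not pass over all families (adjusted p = 0.141). Nlrc5, a regulator of class I genes, had a log2 fold change of -1.48 (SE 0.16). The calls of H2-Aa, H2-Eb1 and Cd74 were lost without control 4, those of H2-Aa and H2-Eb1 also without control 2, and that of H2-Eb1 also without cKO 1, cKO 2 or cKO 4.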
